A study of Glycine max with 11 samples.

How the data were processed

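RNA of etiolated soybean hypocotyls was hybridised to 11 spotted cDNA arrays with 2 channels and 19200 spots in 48 print blocks, each array carrying Harosoy63 and Harosoy. Groups, replicate numbers and the dye of each cultivar were taken from the labels: 5 infected times with 2 biological replicates each and 1 water-inoculated array in the dye order of the second replicates. The analysis plan, the fixed gene lists, the rule for named genes and the main alternatives were chosen before the data were examined.

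The deposited intensity columns, per the file headers, are spot volumes and local backgrounds for a Ctrl and a Data block, and the largest values fit a volume of 0.0064 per scanner level with a ceiling of 65535 levels. The deposited background-subtracted intensity is the volume minus background with values under 0 set to 0. The file headers also give a signal-to-noise score per spot, deposited with the volumes, and a percent of saturated pixels, deposited per channel. The spot flag, deposited as a code, was 0 for all spots. The authors' value table holds log2 ratios that match the log2 of the Data over the Ctrl volume without background subtraction or centring for 19200 of 19200 spots within 1e-06; its scale and direction of blocks are thus known, and its columns have medians from -0.86 to 1.41. Per the labels' series text the authors analysed background-subtracted values in GeneSpring; the scanner and image software are not given in the sources used here. In 2 files the scanner header carries another slide number than the sample title.

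Each probe's gene came from the supplied platform annotation: 1158 probes had 1 symbol, 13 several and 17478 clone spots none, and the symbols of 1153 probes matched the RefSeq gene table (assembly Glycine_max_v4.0, used for names only; no coordinates are printed). Probes with several symbols are not named. Members of the 26 fixed lists were assigned by symbol after the names, but before any test result, had been seen; 18 lists with at least 3 measured genes were tested, and 8 were not, among them pathogen sequences, which had no symbol.

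Volumes were divided by the volume of 1 level and corrected with normexp (offset 50); that the offset is added on the level scale was settled after the files had been opened, and moves many counts. Ratios were normalized by loess within each array with control spots at weight 0. Spots of 1 probe were averaged, and probes above background (signal-to-noise of at least 2) in either channel on at least 2 arrays were kept, which left 16098. Ratios were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on group means plus a dye term, with 4 residual and 3.07 prior degrees of freedom. Because the dye order is the replicate number, the dye term is also the replicate block of that fit. Deviations of same-numbered arrays correlated by 0.358 to 0.677 in 10 of 10 pairs of times. Infected against water, and 48 h against 3 h, came from a separate-channel fit after Aquantile scaling, with the intraspot correlation of 0.785 and a dye term, with 9 residual and 5.17 prior degrees of freedom. Each comparison was adjusted by the Benjamini-Hochberg method, and a probe is called at an adjusted p under 0.05. Lists were tested with camera at a preset correlation of 0.01, averaging probes of 1 gene, and again with an estimated correlation; 14 calls of 396 tests were made with the preset and 0 with the estimate. P-values rest on 1 spread per probe, pooled over the groups after the dye term. In the ratio fit that term also takes out a difference common to the 2 replicate series. The water array adds nothing to the spread, and the number of arrays per group limits the precision.

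Named genes follow the rule: for cultivar ratios the 5 highest and 5 lowest named genes of those called and in 1 direction on both arrays (at least 9 of 10 for the mean), for changes within a cultivar the 8 highest and 8 lowest with all channels on 1 side, up to 4 members of each list by size of change in the mean ratio and the 48 h ratio, and where none passed the 3 highest and 3 lowest by p. For each gene the probe with the largest mean signal is given. The text gives "at least N-fold" where a probe was not above background in any channel of the dimmer group. It does so too where the probe was saturated (any saturated pixel) in all channels of the brighter group. The value is the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal above background and the probe's own. This is per channel and open to dye bias where swaps are unbalanced. It carries no standard error. Where the probe's own signal is used, or some channels of the dimmer group held saturated pixels, it is an estimate rather than a strict limit. Every alternative was refitted with 1 choice changed, except that the authors' value table, centred by the array median, leaves out background correction and loess together. Where only some channels of a group were above background, the text says how many for single times and 48 h against 3 h. Another 3 alternatives, the clone sets, the offset on the volume scale and the removal of both second arrays at 24 h and 48 h, were chosen after seeing the data. So was the definition of the clone sets (over 0.25 of at least 30 measured clones called one way at 48 h). A set of 96 takes alternate rows and alternate places of a run of 384 consecutive clone numbers of 1 library.

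The fits were tested on simulated data for 16098 probes. The simulated noise was independent between probes and arrays, and the dye effect was equal on all arrays. Background correction and loess were not part of it. It thus does not cover effects of single arrays or of replicate series. Of probes changed by log2 of 1 and 2, 139 and 181 of 200 were recovered for the 24 h cultivar ratio, 92 and 100 of 100 for the mean, 7 and 80 of 200 for the susceptible cultivar at 24 h against water, 3 and 55 of 100 for its mean and 0 and 44 of 100 in the F-test, with 19, 14, 5, 8 and 4 calls elsewhere.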

Results

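The arrays compared gene expression in dark-grown (etiolated) soybean hypocotyls of 2 cultivars, Harosoy63, whose response to the oomycete root and stem rot pathogen *Phytophthora sojae* is resistant per the labels, and Harosoy, whose response is susceptible. Each of 11 spotted arrays carried RNA of both cultivars, one in the Cy3 and one in the Cy5 channel. Hypocotyls inoculated with race 2 of the pathogen were taken at 3, 6, 12, 24 and 48 h, with 2 replicates per time that the labels call biological and with the dyes exchanged on the second. The remaining array held water-inoculated tissue of both cultivars. Its title gives 3 h and the series text 0 h, so it is called the water array here. Between 67.0% and 84.0% of spots per array were above background in the Cy5 channel and between 23.5% and 76.3% in the Cy3 channel, the lowest being the second 48 h array. Of 16098 probes measured, 989 carried a gene symbol, for 490 genes.

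Ratios are Harosoy63 (resistant) over Harosoy (susceptible), as log2 with the standard error of the fit. The assignment of the scanner's 2 blocks to Cy3 and Cy5 is likely rather than stated: it rests on the channel order in the labels and on the deposited ratio being the second block over the first. The other assignment would turn every cultivar direction given here, and would exchange the resistant and susceptible names of all changes within a cultivar, counts included. Correlations of the deposited ratios across probes, which are not independent replicates, were 0.197, -0.029, 0.416, -0.42 and -0.386 between the 2 replicates at 3, 6, 12, 24 and 48 h. With exchanged dyes a cultivar difference shared by both replicates lowers these values, and a dye effect shared by both raises them. After normalization and turning to resistant over susceptible, the correlations were -0.095, 0.053, 0.045, 0.373 and 0.221. Over pairs of arrays, the turned ratios had a median correlation of 0.257 in the same dye order. It was -0.2 in opposite orders at different times.

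Between the cultivars during the first 12 h of infection, no gene passed the test. At 3 h the smallest p-values above 0 on the log2 scale belonged to AOX3 (1.31 ± 0.20), the peroxidase PRX4 (0.87 ± 0.15) and BZIP109 (1.56 ± 0.32). Those below 0 belonged to the seed maturation gene PM30 (at least 1.6-fold, not well above background in the resistant channels), LOC547898 (at least 1.71-fold, saturated in the susceptible channels) and the vegetative lipoxygenase VLXB (-0.60 ± 0.13), all at adjusted p of 0.22 to 0.24. At 6 h these were LOC548088 (ODC1; 1.75 ± 0.22), the peroxidase LOC547499 (GMIPER1; 1.31 ± 0.17), PRX4 (at least 1.93-fold, saturated in the resistant channels), the aquaporin PIP2-6 (-1.38 ± 0.20), LOC547898 (-0.92 ± 0.15) and LOC547893 (-0.90 ± 0.15), each at adjusted p = 0.12, with saturated pixels in 1 of 2 resistant channels for LOC548088 and LOC547499 and in 1 of 2 channels of each cultivar for LOC547898, which was above background in 1 of 2 resistant channels. At 12 h they were BZIP62 (0.85), LOC548073 (0.96 ± 0.22), the superoxide dismutase SODB (0.88 ± 0.20), LOC547898 (-1.0 ± 0.15), the vegetative storage protein LOC547820 (VSPB; -0.73 ± 0.14) and PGM (-0.59 ± 0.14), LOC547898 and LOC547820 with saturated pixels in 1 of 2 channels of each cultivar. With limma, 0 probes passed at each of 3, 6 and 12 h, and 1853, 2122 and 1749 had an unadjusted p under 0.05. Each of these is a larger share of the 16098 probes than 0.05. The counts of 0 thus do not show that the cultivars were alike at these times. Without the second 3 h array 15 probes passed at 3 h, without the second 6 h array 1 passed at 6 h, and with the normexp offset added on the deposited volume scale 67 passed at 6 h.

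As groups, the 19 measured genes of phenylpropanoid and isoflavonoid synthesis, the route to the soybean phytoalexin glyceollin, had a median ratio of 0.40 at 3 h (camera, adjusted p = 0.0054) and 0.20 at 6 h (adjusted p = 0.046), with 17 of 19 genes above 0 at both times. With an estimated correlation the adjusted p was 0.96 at 3 h and 0.99 at 6 h. The 30 genes for WRKY, MYB, NAC and related regulators had a median of -0.13 at 3 h and the 24 seed and vegetative storage genes one of -0.17, each at adjusted p = 0.046 and at adjusted p = 0.96 with an estimated correlation. The 11 lipoxygenase and jasmonate genes had a median of -0.22 at 12 h (adjusted p = 0.046; adjusted p = 0.96 with an estimated correlation). No single member of these lists passed over all probes. Adjusted over the list alone, 0 phenylpropanoid genes passed at 3 h and 2 at 6 h, 1 storage gene passed at 3 h, and 0 genes of the other 2 lists passed.

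At 24 h the resistant cultivar had higher signal for the class III peroxidase PRX2 (3.22 ± 0.40, n = 2 arrays, adjusted p = 0.022), LOC547843 (2.25 ± 0.52), LOC547872 (2.17 ± 0.35) and LOC547871 (1.95 ± 0.37). LOC778108 was at least 3.6-fold higher (fitted 1.85 ± 0.37), being not above background in the susceptible channels. Lower in the resistant cultivar were PGIP, a polygalacturonase-inhibiting protein that acts against pathogen pectin-degrading enzymes (-2.40 ± 0.34, adjusted p = 0.023), the glutathione S-transferase GSTU41 (-1.92 ± 0.39), the ABC transporter PDR12 (-1.71 ± 0.33), the calcium pump SCA1 (-1.50 ± 0.30) and ACS1 (-0.94 ± 0.18). In the dimmer cultivar, LOC547843, PDR12 and SCA1 were above background in 1 of 2 channels. The 2 other PRX2 probes did not pass, and ACS1 lies in 1 of 3 clone sets described under the 48 h ratios. Of 6 peroxidase genes 2 were higher and 0 lower; adjusted over the list alone, 3 were higher and 2 lower. Of 11 lipoxygenase and jasmonate genes 3 were higher and 0 lower; adjusted over the list alone, 4 and 1. None of the 19 phenylpropanoid genes passed, nor any over the list alone.

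In all, 1080 probes differed at 24 h, 753 higher and 327 lower in the resistant cultivar. That count was 0 without the dye term, which in the ratio fit is also the replicate block. Every 24 h ratio was then the same and the median standard error rose from 0.17 to 0.239, for PRX2 from 0.40 to 0.68 (adjusted p = 0.12). The count was 67 with plain background subtraction, 455 with the offset on the volume scale and 1959 without the second 24 h and 48 h arrays. Leaving out 1 array gave 1 without either 6 h array, 28 without either 12 h array, 2 and 229 without the first and the second 24 h array, and 2673 without either 48 h array. Leaving out the water array, or the other array of another time, repeats a fit, which leaves 6 different ones. PRX2 and PGIP passed in 3 of these 6, GSTU41, PDR12, SCA1, LOC547871, LOC547872 and LOC778108 in 2 and LOC547843 and ACS1 in 1.

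At 48 h LOX7, a lipoxygenase, was higher in the resistant cultivar by 2.42 ± 0.28 (adjusted p = 0.0054, n = 2), and the seed lipoxygenase LOC547835 (loxA), saturated in both resistant channels, was at least 4.47-fold higher (adjusted p = 0.0053). Lipoxygenases are enzymes of fatty acid oxidation and of jasmonate synthesis. Of the 11 lipoxygenase and jasmonate genes 5 were higher and 1, the allene oxide synthase AOS1, was lower (-2.09 ± 0.14); adjusted over the list alone, 7 were higher and 2 lower. The list as a whole did not pass (median 0.39, adjusted p = 0.52). PRX2 (2.91 ± 0.40), PRX2B (1.57 ± 0.23) and LOC547499 (at least 1.88-fold, saturated in the resistant channels) made 3 of 6 peroxidases higher, also 3 adjusted over the list alone. None of the 2 other PRX2 probes or the 1 other LOC547499 probe was above 0. LOC778108 was at least 3.16-fold higher and LOC547759 higher by 2.17 ± 0.32. LOC100037461, saturated in the resistant channels, was at least 4.98-fold higher, and 1 of its 2 other probes lay on the same side.

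Further genes higher at 48 h were the vegetative storage protein LOC547820 (1.73 ± 0.14), sucrose synthase SS (1.71 ± 0.29), PGM (1.22 ± 0.14), ascorbate peroxidase APX2 (at least 3.3-fold, saturated in the resistant channels), SODB (0.98 ± 0.20), the ethylene-response factors EREBP1 (1.40 ± 0.19) and EREB (1.04 ± 0.19), MYB175 (1.28 ± 0.25), PIP2-6 (0.88 ± 0.20) and BG7S-1 (0.63 ± 0.12, a sign that turned without background correction and with the authors' table). The 4-coumarate:CoA ligase 4CL2 was at least 1.38-fold higher. Lower were GSTU41 (-1.74 ± 0.39), MYB176, a regulator of isoflavonoid synthesis (-1.27 ± 0.14), MS (-2.49 ± 0.44), LOC732571 (-3.26 ± 0.20, saturated pixels in 1 of 2 susceptible channels), LOC548016 (-2.62 ± 0.16), PDK3 (-2.50 ± 0.18) and the galactinol synthase GOLS (at least 3.15-fold). The other MYB176 probe passed in the opposite direction (1.15, adjusted p = 0.0089), so the direction of this gene stays open, and 11 of 95 probes of the clone set that holds MYB176 were lower and 8 higher. PM30 passed as lower and LOC547576 (GSTU3) as higher, with no fold given: PM30 was not well above background in any channel, and LOC547576 in none of the susceptible ones, with a bound under 1. In the dimmer cultivar, PRX2, LOC547759, SS, PGM, SODB, EREBP1, BG7S-1 and MS were above background in 1 of 2 channels. By list, 3 redox genes were higher and 1 lower of 23 (4 and 2 adjusted over the list alone), 3 and 2 of 30 transcriptional regulators (3 and 3), 2 and 1 of 24 storage genes (2 and 1), 2 and 0 of 9 genes of sugar metabolism (2 and 0) and 1 and 0 of 19 phenylpropanoid genes (1 and 0). Medians of the photosynthesis and storage lists, which also mark green and cotyledon tissue, were 0.14 and -0.01.

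Together 1415 probes differed at 48 h, 1080 higher and 335 lower. Of the lower ones, 161 came from 3 sets of 96 consecutively named clones, in which 59.2% of 272 measured probes were lower against 1.1% elsewhere. LOC732571, LOC548016, PDK3, GOLS, AOS1 and ACS1 are in these sets. Of 15 genes with a low probe there, 10 had further probes outside, and those 30 probes had a median of 0.02; GOLS, AOS1 and ACS1 had none. Among them 1 probe of LOC548016 was higher (2.80). The count was 56 without the dye term (no replicate block; same ratios, median standard error 0.239 against 0.17), 183 with plain background subtraction, 538 with the offset on the volume scale and 833 without the second 24 h and 48 h arrays. Leaving out 1 array gave 407 without the second and 2606 without the first 48 h array, 844 without either 12 h array and 835 without either 6 h array. Of the 6 different fits, LOC778108, LOC547759 and MYB176 passed in 6 and LOX7, LOC547835 and PRX2 in 5, but PM30 in 1 and PIP2-6, BG7S-1, GSTU41, MYB175 and LOC100037461 in 2. These fits keep the dye term. Without it LOC778108 still passed in limma (adjusted p = 0.022), but LOX7 (0.067), PRX2 (0.11) and LOC547759 (0.2) did not. Over all cultivar ratios, 6 results for single probes then stayed past the threshold and 65 did not.

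**Figure D1:**
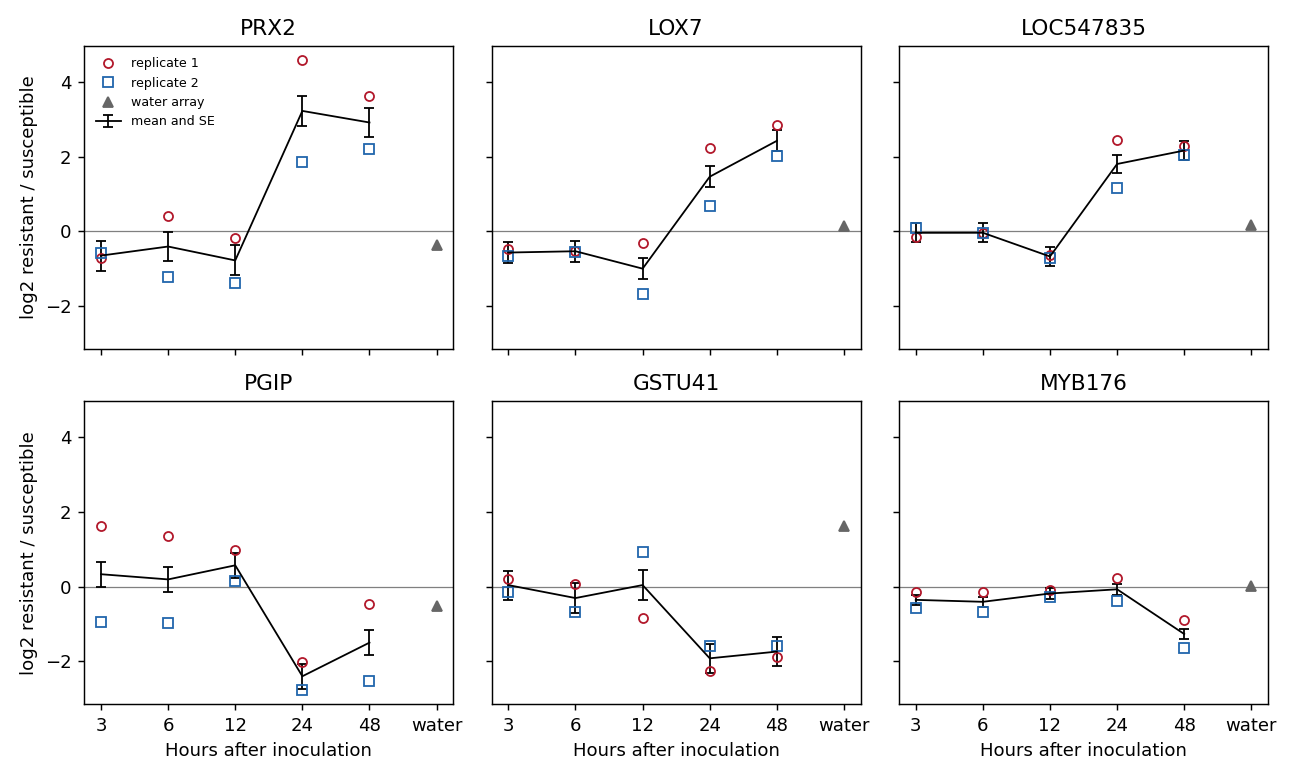
Log2 ratio of resistant over susceptible signal (vertical axis) against hours after inoculation (horizontal axis) for PRX2, LOX7, LOC547835, PGIP, GSTU41 and MYB176; lines join the means of 2 arrays with the standard error of the fit, open symbols are single arrays and the triangle is the water array. PRX2 lies at -0.65 at 3 h and 2.91 at 48 h, and PGIP at 0.33 and -1.50.

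Averaged over the 5 infected times, the largest ratios with a common direction on at least 9 of 10 arrays were those of LOC547752 (0.95 ± 0.21, adjusted p = 0.046), LOC548073 (0.80 ± 0.10, above background in 7 of 10 susceptible channels), the cytosolic glyceraldehyde-3-phosphate dehydrogenase GAPC1 (0.74 ± 0.15), SODB (0.66 ± 0.09) and GND (0.59 ± 0.14), and MYB176 was lower (-0.46 ± 0.06, adjusted p = 0.014). Among the listed genes, PRX2 (0.86 ± 0.18), LOC547499 (0.55 ± 0.08), PRX4 (0.29 ± 0.07), LOC547835 (0.64 ± 0.11), SS (0.63 ± 0.13), 4CL2 (0.55 ± 0.10), the ribosomal protein RPL2 (0.45 ± 0.10) and LOC547820 (0.39 ± 0.06) were higher. The other probe of MYB176, and that of LOC547499, lay on the opposite side. Saturated pixels, which pull a ratio towards 0 where they are in the brighter channel, were present in 5 of 10 resistant and 1 of 10 susceptible channels for GND, 7 and 3 for LOC547499, 6 and 2 for PRX4, 9 and 5 for LOC547835, 5 and 5 for LOC547820, 2 and 0 for GAPC1, 1 and 0 for SS and 0 and 1 for PRX2. GSTU41 (-0.78 ± 0.17), AOS1 (-0.69 ± 0.06) and WRKY13 (-0.31 ± 0.06) were lower, the last 2 within the clone sets. PM30 passed as lower too, with no fold given, as it was above background in 0 of 10 resistant and 2 of 10 susceptible channels. Of 6 peroxidases 3 were higher (4 adjusted over the list alone), with a list median of 0.24 (adjusted p = 0.052). In all 1104 probes differed, 847 higher and 257 lower, 123 of them from the clone sets. Median centring in place of loess gave 2019, plain background subtraction 52 and no dye term (no replicate block) 0, with the same ratios and a median standard error of 0.107 against 0.0759. Without 1 array the count was 22 and 288 (first and second 12 h array), 84 and 615 (24 h), 517 and 475 (3 h), 166 and 27 (6 h) and 3273 (first 48 h array). Of the 10 fits without 1 infected array, LOC548073 and AOS1 passed in 8 and MYB176 in 6, but PRX2, SS and GAPC1 in 3, LOC547752, RPL2, WRKY13 and GSTU41 in 2 and GND and PRX4 in 1.

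The cultivar ratio changed between infected times for 546 probes in an F-test, 393 of them with a higher and 153 with a lower ratio at 48 h than at 3 h. Of 49 named genes with a called probe, those given here were picked by their 24 h or 48 h ratios. The ratio moved from -0.57 to 2.42 for LOX7 (adjusted p = 0.021), from -0.65 to 2.17 for LOC547759 (adjusted p = 0.029) and from 0.33 to -1.50 for PGIP (adjusted p = 0.047). Across probes, which are not independent replicates, ratios at 24 h and 48 h correlated at 0.723 and those at 3 h and 6 h at 0.392. The count was 0 without the dye term (no replicate block; same ratios) or with plain background subtraction, 354 with the offset on the volume scale and 308 without the clone sets. It was 0 without any single 6 h or 12 h array, 170 and 357 without the first and second 24 h array, 316 without the first 3 h array and 1484 without the first 48 h array.

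In water-inoculated tissue, measured on 1 array whose spread is taken from the others, no named gene passed. MAN1 (saturated in both channels, so no fold is given), FAD2-3 (0.78 ± 0.25) and EU3 (0.56 ± 0.19) had the smallest p-values above 0. Those below belonged to PM30 (at least 2.32-fold, not well above background in the resistant channel), ACCB-1 (-2.16 ± 0.36) and the pathogenesis-related PR-10 (at least 4.33-fold, saturated in the susceptible channel). The 19 phenylpropanoid genes had a median ratio of -0.90 (camera, adjusted p = 0.00065; adjusted p = 0.96 with an estimated correlation), with 3 genes above 0 and 0 passing over all probes or adjusted over the list alone. Setting the mean infected ratio against the water ratio, this list had a median of 1.09 (adjusted p = 0.00047; adjusted p = 0.96 with an estimated correlation), with 0 genes passing over all probes and 1 adjusted over the list alone, while its median over the infected times themselves was 0.17 (adjusted p = 0.15). Single genes of that difference did not pass: PM30, which has no measured resistant water level, LOC547499 1.48 ± 0.26, 4CL2 1.79 ± 0.34, GSTU41 -2.24 ± 0.60, LOC547474 -0.71 ± 0.20 and CBP -0.66 ± 0.19. With limma 1 probe passed in water and 1 in the difference, the same unnamed probe, which was not above background in either water channel; unadjusted p was under 0.05 for 1424 and 1970 probes. These counts were 115 and 104 with plain background subtraction, 269 and 375 with the offset on the volume scale, and 0 and 0 with no background correction or the authors' table. Without the second 3 h array the difference gave 17 probes, without the second 12 h array 0, and without either 48 h array 2. The water ratio gave 3 without either 3 h array and 2 without either 48 h array.

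**Figure D2:**
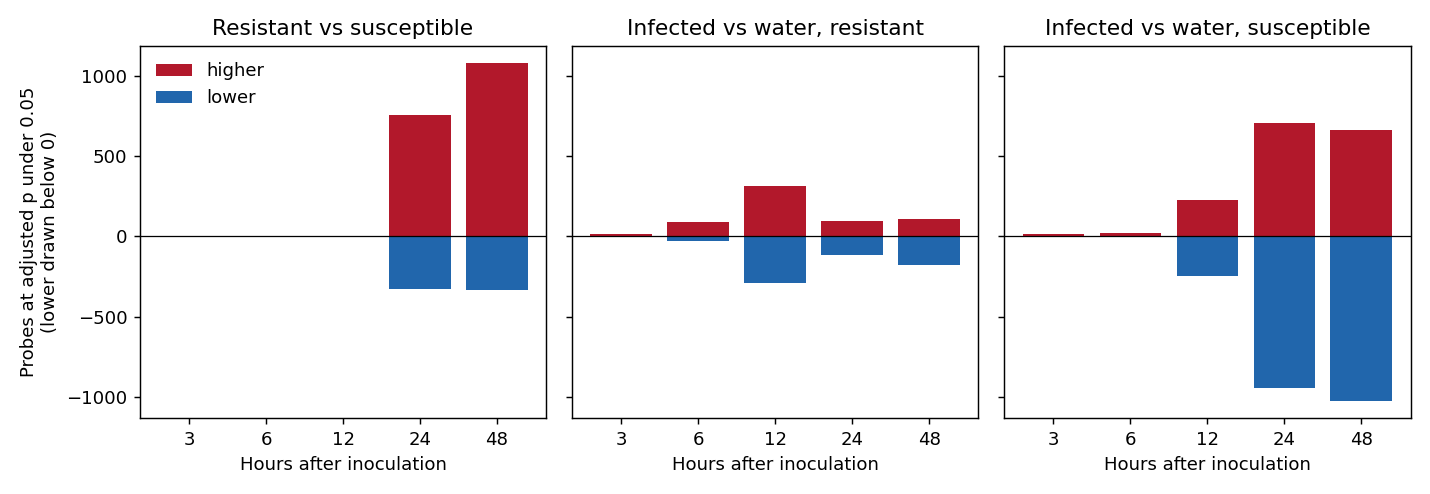
Number of probes at an adjusted p under 0.05 (vertical axis; lower ones drawn below 0) against hours after inoculation for the resistant over susceptible ratio and for infected over water in each cultivar. The cultivar ratio has 0 probes up to 12 h, 1080 at 24 h and 1415 at 48 h.

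The infected times were set against the water array within each cultivar, from the separate channels. That array is of 0 h or 3 h, and no water tissue was measured at 6, 12, 24 or 48 h. An effect of infection thus cannot be told apart from one of time since inoculation in these changes. The same holds for the mean infected ratio set against the water ratio above. In the resistant cultivar, averaged over the 5 times, the 4-coumarate:CoA ligase 4CL3 rose by 3.52 ± 0.82 (adjusted p = 0.049), the peroxidase LOC547499 by 3.08 ± 0.37 (adjusted p = 0.0012) and the peroxidase PRX4 by 2.06 ± 0.39. PR-10, saturated in 10 of 10 infected channels, rose at least 7.54-fold (adjusted p = 0.022). Saturated pixels were also present in 7 of 10 infected channels for LOC547499, 6 for PRX4 and 3 for GSTF5. Glutathione S-transferases GSTU17 (2.75 ± 0.52) and GSTF5 (2.19 ± 0.47) and the catalase CAT1 (2.57 ± 0.55) rose too, and MAN1, saturated in the water channel, fell at least 6.11-fold (adjusted p = 0.00034). The other probe of LOC547499 and that of CAT1 lay on the opposite side. The phenylpropanoid list had medians of 0.91, 1.74, 1.83, 1.38 and 1.14 at 3, 6, 12, 24 and 48 h and 1.41 over the times (camera, adjusted p = 3.2e-05; adjusted p = 0.57 with an estimated correlation). At the single times its adjusted p was 4.8e-05, 6.9e-07, 3.2e-05, 0.00062 and 0.031, and with an estimated correlation adjusted p = 0.57 up to 24 h and adjusted p = 0.72 at 48 h. For the mean, 1 of its 19 genes passed over all probes and 6 adjusted over the list alone, and 16 were above 0. Of 6 peroxidases 2 rose, and 2 rose and 1 fell adjusted over the list alone; of 23 redox genes 3 rose, 4 over the list alone.

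For the resistant cultivar the mean called 232 probes, 139 higher and 93 lower, and the times 14, 120, 604, 210 and 285. Channels scaled by the array median gave 68 for the mean, 51 higher and 17 lower, or 75% higher against 59.9%, while no dye term gave 368, the offset on the volume scale 380 and leaving out the second 24 h and 48 h arrays 35. Without 1 array the mean gave 67 and 52 (12 h), 40 and 36 (24 h) or 89 and 84 (6 h); in these 10 fits, none of which leaves out the water array, LOC547499 and MAN1 passed in 10, PR-10 in 8, PRX4 in 7, GSTU17 in 5, CAT1 in 4, GSTF5 in 3 and 4CL3 in 2. All these changes share the single water array, so its own deviation enters each of them, and the water ratio of this list given above enters them too.

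In the susceptible cultivar GSTU17 rose at least 6.01-fold over the mean of the times (adjusted p = 0.011), and CAT1 (2.14 ± 0.55), LOC732556 (1.88 ± 0.34), the photosystem I subunit PSAD (1.46 ± 0.34) and COPZ2 (1.36 ± 0.32) rose. The transcription factors BZIP117 and NAC3 rose at least 3.8-fold and 3.76-fold, and the heme oxygenase HO1 at least 1.39-fold. None of the 2 other PSAD probes, the 1 other NAC3 probe or the 1 other CAT1 probe lay on the same side. MAN1 fell at least 4.32-fold (adjusted p = 0.0045) and CEL12 of the cell wall list at least 3.76-fold, both saturated in the water channel. LOC778079 (-1.52 ± 0.38), the peroxidase PRX3 (-1.45 ± 0.37) and LOC547883 (-1.39 ± 0.34) fell, above background in 3, 6 and 9 of 10 infected channels. The phenylpropanoid list had a median of 0.44 (adjusted p = 0.47), with 0 of 19 genes passing over all probes or adjusted over the list alone; its difference between cultivars is the 1.09 given above. Of 6 cell wall genes 1 fell (2 over the list alone) and 0 rose, and of 23 redox genes 2 rose (4 over the list alone, with 1 lower).

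The mean called 522 probes in the susceptible cultivar, 219 higher and 303 lower, and the times 16, 18, 475, 1652 and 1692. Channels scaled by the array median gave 209 for the mean, the offset on the volume scale 870 and leaving out the second 24 h and 48 h arrays 67. Without 1 array the mean gave 209 and 202 (12 h), 137 and 228 (24 h), 290 and 167 (3 h) or 249 and 280 (6 h), and 24 h gave 334 and 909 without its own arrays. MAN1, GSTU17, BZIP117 and LOC732556 passed in all 10 fits, each of which keeps the same water channel, but CEL12 and PSAD in 3, CAT1, NAC3, COPZ2, LOC778079 and LOC547883 in 2, PRX3 in 1 and HO1 in 0.

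**Figure D3:**
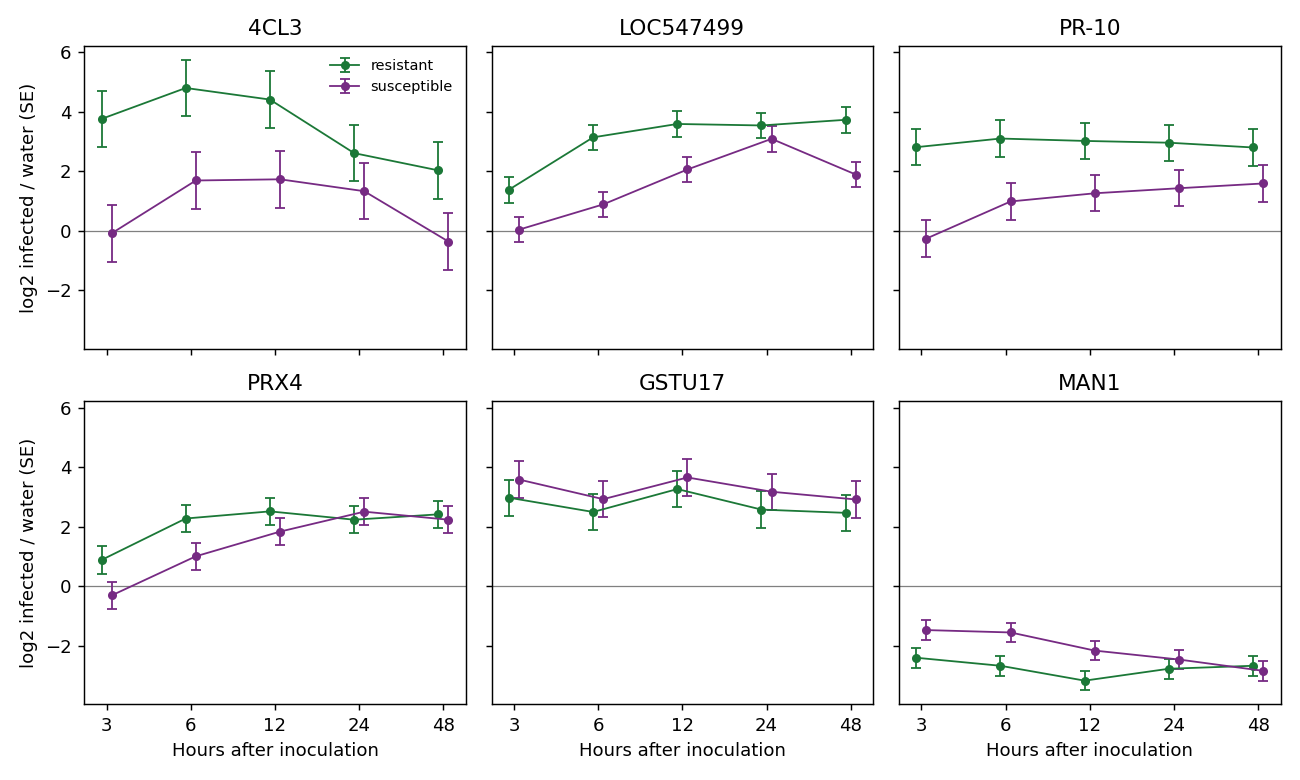
Log2 change from the water array with its standard error (vertical axis) against hours after inoculation for 4CL3, LOC547499, PR-10, PRX4, GSTU17 and MAN1 in the resistant and the susceptible cultivar (2 channels per point against 1 water channel). Averaged over the times LOC547499 lies at 3.08 in the resistant cultivar. PR-10 and MAN1 hold saturated groups, as do LOC547499 at 48 h and PRX4 at 6 h in the resistant cultivar.

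From 3 h to 48 h, a comparison without the water array, p20-1 of the protease inhibitor list rose in both cultivars, by 3.11 ± 0.60 in the resistant (adjusted p = 0.018) and by 4.22 ± 0.60 in the susceptible one (adjusted p = 0.0013), with saturated pixels in 1 of 2 channels at 48 h in each. No water tissue was measured at 48 h, so changes from 3 h to 48 h cannot be ascribed to infection rather than time. In the resistant cultivar LOC547499, saturated at 48 h, rose at least 5.1-fold and LOC547628 by 1.19 ± 0.27. The auxin-regulated ADR11 and PEPC17, both saturated at 3 h, fell at least 28.7-fold and 10.2-fold, and AG1 (-3.43 ± 0.67) and LOC548088 (-2.30 ± 0.41) fell. In the susceptible cultivar PRX4 (2.54 ± 0.37), IFR1 of isoflavonoid synthesis (2.11 ± 0.61) and the beta-amylase LOC547684 (1.94 ± 0.49) rose, and MS rose at least 3.52-fold. LOC732571 (2.73 ± 0.50), ACS1 (2.26 ± 0.41) and PDK3 (1.93 ± 0.45), all in the clone sets, were higher as well. ADR11 fell at least 21.1-fold there and LOC778108 at least 4.91-fold, with AG1 (-3.92 ± 0.67), PEPC17 (-3.82 ± 0.79), PRX2 (-3.65 ± 0.70), the glutamate decarboxylase LOC547724 (-3.36 ± 0.91), LOC547871 (-3.25 ± 0.60) and LOC547843 (-3.16 ± 0.88) also lower. In this cultivar 1 of 2 channels held saturated pixels for LOC732571 at 48 h and for ADR11, PEPC17 and PRX2 at 3 h. In the dimmer group 1 of 2 channels was above background for ACS1 at 3 h, for AG1, PEPC17, PRX2, LOC547724, LOC547871 and LOC547843 at 48 h, and for AG1 at 48 h in the resistant cultivar.

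By list, 4 of 11 lipoxygenase and jasmonate genes fell and 1 rose in the susceptible cultivar from 3 h to 48 h, the same counts adjusted over the list alone, and 0 passed in the resistant one either way. The 3 measured receptor and resistance kinases had a median of -0.77 in the resistant cultivar (camera, adjusted p = 0.039; adjusted p = 0.18 with an estimated correlation), with 0 members passing over all probes or adjusted over the list alone. In all 287 probes changed in the resistant cultivar, 80 higher and 207 lower, and 1457 in the susceptible one, 483 higher and 974 lower. Plain background subtraction gave 133 and 437, and leaving out the second 24 h and 48 h arrays 13 and 325; the offset on the volume scale gave 599 in the susceptible cultivar. Without the first or second 3 h array the counts were 79 and 83 in the resistant and 347 and 652 in the susceptible cultivar, without the first or second 48 h array 169 and 49 and 2354 and 398, and without either 24 h array 176 in the resistant cultivar. In the susceptible cultivar p20-1, PRX4, ADR11 and LOC778108 passed in 7 of the 7 different fits, but LOC547724 in 2 and IFR1 and LOC547843 in 1. In the resistant cultivar LOC547499 passed in 5, p20-1 in 3, PEPC17 in 2 and LOC547628 in 0.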

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

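The weighing of the dim Cy3 channel, the 16 splits with balanced dyes and the standard errors without the dye term were chosen after a result had been seen, and the 100 drawn splits before.

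The cultivar ratio differed between infected times for 546 probes in the moderated F-test and between infected and water tissue for 1 probe. In the F-test 49 named genes had a called probe. Those given here were also picked among the largest called ratios at 24 h or 48 h and lie outside the clone sets. Their choice thus used values that enter the F-test. Their log2 changes from 3 h to 48 h were PRX2 (3.56), LOC778108 (4.83, a fitted value of a probe near background, so no bound), LOX7 (2.99), LOC547759 (2.82) and PGIP (-1.83). Spots named Empty, which the comparisons do not use, were above background at a median of 21.0% per array (18.6% to 23.4%), against 0% to 1.82% of spots named Blank.

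The called cultivar differences, 1080 probes at 24 h and 1415 at 48 h after 0 at each earlier time, fall at the 2 times whose second arrays had the lowest median Cy3 levels (2325 and 1954). By spots above background in Cy3 the second 24 h array does not stand out. It had 51.4%, against 50.5% on the second 6 h array and 23.5% on the second 48 h array. At 24 h and 48 h the dimmer channel was the susceptible one in both dye orders. Susceptible against resistant median levels were 2364 against 3967 and 2311 against 3251 on the first arrays. On the second arrays they were 2325 against 6330 and 1954 against 4811. The susceptible channel was also the dimmer one on both arrays at 3 h and 6 h, where 0 probes were called. The count at 48 h without the second 24 h and 48 h arrays, given above, cannot decide whether a dim channel is the cause. The first arrays kept at these times also have a dimmer susceptible channel, and 1 array remains at each. Of 100 drawn ways of assigning the cultivars to the channels of infected arrays, 1, the real one, called as many probes for the mean of the times (1104; the highest other was 268). That met the bound set beforehand for excluding chance. Only 1 other drawn split kept balanced dyes at all 5 times, and whether imbalance lowers the count was not tested. The standard error of the mean ratio per unit of spread was 1.05 times the real one, at the median of the other drawn splits. Chance is not taken as excluded, given the balanced splits that follow. The 16 splits that exchange both arrays of a time keep the dyes balanced. Of these splits 5, the real one included, called as many (the highest other was 1808). These 16 are too few for a share under 0.05, and a cultivar difference that changes with time also enters them. Without the dye term the real assignment called 0 probes for the mean ratio. Its median standard error rose from 0.0759 to 0.107 while every ratio stayed the same. That term is also the replicate number, so its removal returns a dye effect and a difference between replicates alike to the error. The count of 0 cannot tell these apart. If the term holds a difference between biological replicates, the called probes rest on a spread that leaves it out. The count of 1 at 24 h without either 6 h array shows how far single arrays set the spread, and a cultivar difference in the response remains a hypothesis. Whether the tissue taken differed between cultivars was not tested.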

How the results depend on the processing

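The clone sets, the offset on the volume scale and the removal of both second arrays at 24 h and 48 h were chosen after seeing the data, and the cause of the changes below was not tested except that fewer arrays were fitted where arrays were left out. Of 274 named results, 43 turned sign at least once, 102 times in all, 33 of them with 1 array left out; 3 of these concerned results past the threshold, BG7S-1 in 2 settings and an unnamed probe in 1. For results past the threshold, 2211 of the refits were past it too, in the same direction, and 875 were not; with 1 array left out these were 921 and 489, with 0 turned, repeated fits included. The authors' value table changes background correction and loess together. Without the dye term the cultivar ratios at single infected times stay as they were and their median standard error rises from 0.17 to 0.239. An arm left with 1 array is assumed to vary like the other groups. The alternative that keeps marked spots was not run because 0 spots carry a mark. No setting but plain background subtraction moved the median of all probes by over 0.1, by -0.11 for the F-test ratio. The channel fit held no replicate block. Deviations of same-numbered arrays in mean intensity correlated by -0.076 to 0.334, above 0.1 in 4 of 10 pairs of times. Whether the replicate numbers pair samples there thus stays open. A replicate block there gave, for example, 770 probes for resistant 12 h and 1970 for susceptible 24 h and moved no count by over 1.5 times. Signal over background limits the second 48 h array most, at 23.5% of Cy3 spots.

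With the authors' value table the count was 6 for the ratio at 6 h, 0 for the water ratio and 0 for infected minus water. With channels scaled by the array median the count was 67 for resistant 6 h, 318 for resistant 12 h, 119 for resistant 24 h, 152 for resistant 48 h, 68 for resistant mean and 8 for susceptible 3 h. Also, it was 256 for susceptible 12 h and 209 for susceptible mean. With trend and robust eBayes the count was 1 for the ratio at 12 h and 2 for infected minus water. With an estimated correlation the count was 0 for gene lists. With each probe counted the count was 67 for gene lists. With median centring the count was 2019 for the mean ratio and 2 for the water ratio. Without background correction the count was 1 for the ratio at 6 h, 1 for the ratio at 12 h, 0 for the water ratio, 0 for infected minus water, 3 for resistant 3 h and 4 for susceptible 3 h. Also, it was 7 for susceptible 6 h. Without the dye term in the channel fit the count was 184 for resistant 6 h, 362 for resistant 24 h and 368 for resistant mean. Without the dye term of the ratio fit (no replicate block) the count was 0 for the ratio at 24 h, 56 for the ratio at 48 h, 0 for the mean ratio and 0 for the F-test. With the offset on the volume scale the count was 67 for the ratio at 6 h, 455 for the ratio at 24 h, 538 for the ratio at 48 h, 269 for the water ratio, 375 for infected minus water and 354 for the F-test. Also, it was 1 for resistant 3 h, 286 for resistant 6 h, 380 for resistant mean, 48 for susceptible 6 h, 1016 for susceptible 12 h and 870 for susceptible mean. Further, it was 599 for susceptible 48 h vs 3 h. With plain background subtraction the count was 67 for the ratio at 24 h, 183 for the ratio at 48 h, 52 for the mean ratio, 115 for the water ratio, 104 for infected minus water and 0 for the F-test. Further, it was 32 for resistant 3 h, 287 for resistant 12 h, 133 for resistant 48 h vs 3 h, 32 for susceptible 3 h, 78 for susceptible 6 h and 1074 for susceptible 24 h. Also, it was 809 for susceptible 48 h, 437 for susceptible 48 h vs 3 h and 7 for gene lists. With print-tip loess the count was 58 for resistant 6 h and 370 for resistant 12 h. With scale normalization of ratios the count was 2 for infected minus water. Without the clone sets the count was 308 for the F-test and 10 for susceptible 3 h. Without both second arrays at 24 h and 48 h the count was 1959 for the ratio at 24 h, 833 for the ratio at 48 h, 2 for the water ratio, 2 for infected minus water, 8 for resistant 3 h and 27 for resistant 6 h. Further, it was 90 for resistant 12 h, 14 for resistant 24 h, 28 for resistant 48 h, 35 for resistant mean, 13 for resistant 48 h vs 3 h and 9 for susceptible 3 h. Also, it was 10 for susceptible 6 h, 37 for susceptible 12 h, 1022 for susceptible 24 h, 657 for susceptible 48 h, 67 for susceptible mean and 325 for susceptible 48 h vs 3 h.

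With 1 array left out, the lowest and highest counts (array left out) were 0 (6 h array 1) to 1484 (48 h array 1) for the F-test, 0 (12 h array 2) to 17 (3 h array 2) for infected minus water, 9 (24 h array 1) to 18 (3 h array 2) for gene lists and 28 (12 h array 2) to 616 (48 h array 1) for resistant 12 h. Counts were 20 (12 h array 1) to 651 (48 h array 1) for susceptible 12 h, 21 (24 h array 1) to 266 (3 h array 1) for resistant 24 h, 334 (24 h array 1) to 2028 (48 h array 1) for susceptible 24 h and 11 (12 h array 1) to 33 (3 h array 1) for resistant 3 h. Counts were 6 (12 h array 1) to 22 (3 h array 1) for susceptible 3 h, 49 (48 h array 2) to 287 (water array) for resistant 48 h vs 3 h, 347 (3 h array 1) to 2354 (48 h array 1) for susceptible 48 h vs 3 h and 69 (48 h array 2) to 297 (3 h array 1) for resistant 48 h. Counts were 1039 (48 h array 2) to 2209 (48 h array 1) for susceptible 48 h, 34 (6 h array 2) to 201 (3 h array 1) for resistant 6 h, 9 (3 h array 1) to 99 (6 h array 1) for susceptible 6 h and 36 (24 h array 2) to 278 (3 h array 2) for resistant mean. Counts were 137 (24 h array 1) to 715 (48 h array 2) for susceptible mean, 0 throughout for the ratio at 12 h, 1 (6 h array 1) to 2673 (48 h array 1) for the ratio at 24 h and 0 (3 h array 1) to 15 (3 h array 2) for the ratio at 3 h. Counts were 407 (48 h array 2) to 2606 (48 h array 1) for the ratio at 48 h, 0 (3 h array 1) to 1 (6 h array 2) for the ratio at 6 h, 1 (6 h array 1) to 3 (3 h array 1) for the water ratio and 22 (12 h array 1) to 3273 (48 h array 1) for the mean ratio. For resistant 48 h vs 3 h the highest with an infected array left out was 239 (6 h array 1).

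Signs turned as follows. With the authors' value table these were, for the ratio at 48 h FLS1 (0.0289), DFR1 (0.000753), WIN (0.0914), LOC547822 (0.226), PRX4 (0.123), NARK (0.0121), SARK (0.203), CDPK-GAMMA (0.115), CAB3 (0.108), LOC548079 (0.0664), BIP4 (0.0479), HSF-33 (0.116), BG7S-1 (-0.335) and UBC4 (0.0408); they were, for the mean ratio D-II (0.00161), AUX22 (0.037), LOC547819 (0.00543) and UBC4 (0.0261). With median centring these were, for the ratio at 48 h DFR1 (0.102), LOC547822 (0.0641), AUX28 (0.0295), SARK (0.0719) and HSF-33 (0.0574). Others were, for the mean ratio AUX22 (0.0511), NARK (0.0328), HSF-33 (0.0236) and UBC4 (0.00109). Without background correction these were, for resistant mean an unnamed probe (-0.375); they were, for the ratio at 48 h SARK (0.00287) and BG7S-1 (-0.296); they were, for the mean ratio D-II (0.0445), AUX22 (0.0066) and LOC547819 (0.05). With the offset on the volume scale these were, for the mean ratio IFS1 (-0.0449) and ELIP (-0.00383). With plain background subtraction these were, for the ratio at 48 h DFR1 (0.0555), AUX22 (-0.11) and GRR1 (0.487); they were, for the mean ratio D-II (0.0671), COI1 (-0.0849) and LOC547819 (0.0645). With print-tip loess these were, for the ratio at 48 h DFR1 (0.0498), LOC547822 (0.119), PRX4 (0.147), SARK (0.015) and HSF-33 (0.106). Others were, for the mean ratio HSF-33 (0.00168). With scale normalization of ratios these were, for the ratio at 48 h SARK (0.0619) and GRR1 (1.55e-05). Without both second arrays at 24 h and 48 h these were, for the ratio at 48 h CHI1B1 (-0.075), F3H (-0.47), CYP98A2 (0.0252), D-II (0.107), AUX28 (0.397), SARK (0.135), SCA1 (0.0206), LOC547819 (0.137), CHLH (0.107), RPS6 (-0.0907), LOC548014 (-0.136), RPS13 (-0.308), HSF-33 (0.0985), SPCP1 (0.0544), GRR1 (0.00541) and GAPC1 (-0.0249). Others were, for the mean ratio LOC547822 (-0.00139), COI1 (-0.027), AUX22 (0.174) and NARK (0.00601). With 1 array left out, values of the ratio at 48 h ranged from -0.532 to 0.64 for AUX22, from -0.467 to 0.354 for AUX28, from -0.602 to 0.0463 for CHLH and from -0.805 to 0.0398 for CYP98A2. The range was from -1.22 to 0.0441 for D-II, from -0.392 to 0.38 for DFR1, from -0.299 to 1.08 for F3H and from -0.096 to 1.66 for GAPC1. The range was from -0.166 to 0.0328 for GRR1, from -0.182 to 0.0709 for HSF-33, from -0.95 to 0.201 for LOC547819 and from -0.222 to 0.154 for LOC547822. The range was from -0.0856 to 0.69 for LOC548014, from -0.369 to 0.0945 for PRX4, from -0.334 to 0.84 for RPS13 and from -0.0754 to 1.5 for RPS6. The range was from -0.25 to 0.235 for SARK, from -1.03 to 0.132 for SCA1, from -0.608 to 0.0256 for SPCP1 and from -0.752 to 0.277 for WIN. The range was from -0.267 to 3.32 for XET1. With 1 array left out, values of the mean ratio ranged from -0.142 to 0.0919 for AUX22, from -0.0344 to 0.55 for COI1, from -0.0128 to 0.245 for ELIP, from -0.618 to 0.0329 for H4, from -0.206 to 0.0245 for LOC547819, from -0.071 to 0.0286 for NARK and from -0.00461 to 0.163 for PIP2-6.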

Other observations

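Of the tests in this part, the one on other probes of the clones' own genes was chosen after its result had been seen, and those on slide position and dye bias before.

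The cell wall list did not pass in the cultivar ratio at 48 h, with a median of 0.83 (camera, adjusted p = 0.091) over 6 measured genes and values of 1.53 ± 0.77 for the xyloglucan endotransglycosylase XET1 (-0.27 to 3.32 with 1 array left out; saturated pixels in 1 of 2 resistant channels), 1.1 ± 0.29 for the proline-rich protein SBPRP, 0.81 ± 0.25 for the expansin EXP1 and 0.74 ± 0.22 for CEL12, the last 3 above background in 1 of 2 susceptible channels. None passed over all probes and 3 were higher adjusted over the list alone. At 24 h the median was 0.78 (adjusted p = 0.058) with 2 higher over the list alone. From 3 h to 48 h the list median was -1.20 in the susceptible cultivar and -0.09 in the resistant one (adjusted p = 0.20 and 0.45).

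Other lists at 48 h did not pass. Median ratios were 0.44 for peroxidases, 0.26 for redox genes, -0.12 for the flavonol branch, -0.24 for pathogenesis-related genes, -0.20 for protease inhibitors, -0.05 for auxin genes, 0.05 for calcium signalling, -0.15 for cytochrome P450, -0.19 for resistance and receptor kinases, 0.25 for ribosomal proteins, 0.15 for sugar metabolism and 0.25 for the housekeeping genes GAPC1, TUBB3 and EF1BGAMMA4. Among members that did not pass, CHI1B2 had 2.36 ± 0.72, LOC547659 1.36 ± 0.45, COI1 1.5 ± 0.50, VSPA 1.29 ± 0.42 and p20-1 -1.12 ± 0.35, with saturated pixels in 1 of 2 channels of each cultivar for p20-1 and of the resistant one for LOC547659. CHI1B2 was above background in 1 of 2 susceptible channels and COI1 in 1 of 2 of each cultivar.

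In the 3 sets of 96 clones, 161 of 272 measured probes were lower in the resistant cultivar at 48 h. The set median was -0.99 against 0.02 elsewhere, and 91 of the probes that changed over time lay in the sets. Of 15 genes with a low probe there, 10 had 30 other probes outside the sets, 14 of them of 1 gene. That these 10 genes were themselves lower by the set median is argued against by a median of 0.0178 over those probes (0 lower, 5 higher) and of -0.07 over the medians of the 10 genes (quartiles -0.22 and 0.08, lowest -0.35, with 6 below 0). For the other clones of the sets this was not tested. A position effect on the slide is argued against by the 547 clones on neighbouring spots, whose median was 0.0817, and the members are spread over 24 print blocks. Material shared by the clones of a plate may be involved and was not tested, nor was any other biological explanation.

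Ratios at 6 h correlated across probes at -0.343 with those at 24 h and at -0.25 with those at 48 h, between means that balance the dyes. Between single arrays of the same dye order the values were -0.159 and 0.233 for 24 h and -0.096 and 0.164 for 48 h, and between arrays of opposite order -0.366 and -0.466, and -0.18 and -0.482. Single arrays at 12 h of the same dye order had 0.267 and 0.197 for 24 h and 0.297 and 0.114 for 48 h. Those of opposite order had -0.0669 and -0.45, and 0.0284 and -0.414. The means at 12 h that balance the dyes had -0.071 and -0.004, and the median over all balanced means was -0.16. A dye effect that is equal on all arrays cancels in these means, so it is not the source of the negative values at 6 h. The bounds set for dye bias were a median above -0.15 with it and below -0.3 without it, and the value lies between. A dye effect that differs between arrays cannot be told apart from a change of the cultivar difference with time, because each time holds 1 array per dye order.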
